A study of Homo sapiens with 4 samples.

How the data were processed

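RNA was taken from H1155 cells carrying an empty lentiviral vector (2 libraries) or a chimeric transcription factor (2 libraries). Per the labels' protocols, total RNA was extracted with a column kit and poly-A RNA was made into strand-specific libraries (TruSeq Stranded mRNA). Per the submitters' processing notes, Trim Galore 0.6.4, STAR 2.7.3a, featureCounts, Subread 1.6.3 and DESeq2 were used with build GRCh38. Their roles and settings, the annotation, and the treatment of strand and of reads that map to several places are not given in the sources used here, so values of genes with near-identical copies (ribosomal protein, histone, tubulin and heat shock genes with pseudogenes) and of overlapping or antisense genes are uncertain. Among rows above 0 in all libraries, 45 had values identical to those of another row.

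The deposited table is named for normalized counts, but the values are TPM: each library summed to 1000000. TPM relates reads to gene length and to the library's total, so a change in a few abundant genes moves all others. Within each gene the 4 deposited TPM values stood in ratios of whole numbers, and whole reads were recovered from them for 18830 of 18830 genes (100.0%; tolerance 0.0001 of a read), up to a common factor per gene, so that the recovered totals are lower bounds. On simulated data the recovery gave the right ratios for 100.0% of 18340 genes and the exact reads for 89.5%. Across 13097 genes, which are not independent replicates, transcript length and the inverse of the worth of 1 read had a Spearman rho of 0.75. The recovered reads set the depth per library given with the results. Gene symbols were matched through RefSeq tables of GRCh38.p14 (18151 of 18830 rows), which also gave the coordinates, 1-based from gene start to gene end. Of 823 entries in 32 gene lists 762 were found in the table.

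Groups were taken from the labels. The test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1) with a variance trend, over 14550 genes with a mean of at least 10 recovered reads after scaling to equal depth, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual and 3.92 prior degrees of freedom, and the median SE was 0.16. A difference on this scale understates the change of genes near 1 TPM. The limit of 10 was fixed before the data were examined, for a table of counts, and was applied to recovered reads once the unit proved to be TPM. A limit of 10 on the mean TPM was added as an alternative. Gene lists with at least 5 tested members were compared with other genes by camera (preset correlation 0.01, two-sided), and by camera with an estimated correlation and fry, with adjustment over 29 lists. With an estimated correlation, camera refers its statistic to the 2 residual degrees of freedom, so a list needs a very large difference to pass. fry tests whether a list's genes move one way on balance and does not compare the list with other genes. Standard deviations are over the 2 libraries of a group, SE and 95% intervals are from limma, and figures were drawn with matplotlib 3.10.9.

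The lists, the test and the rule for naming genes were fixed before the data were examined. The rule named up to 8 genes at each end among genes past the threshold with a mean of at least 50, up to 3 such members of each list or else the member with the most reads, and 16 lineage genes in any case. Values of some genes this rule names are not reported here. Since 0 genes passed, its first part gave none, and other genes are said to be, or were, chosen after their values were seen: the members with the largest differences in each called list, genes called adjusted over the list alone and some members of the stress response list. Adjustment over a list alone does not correct for the number of lists. Of the 29 tested lists each is reported once.

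On simulated data for 14550 genes in the same design, limma called 0 of 50 genes changed 1.5-fold, 34% of those changed 2-fold, 74% of those changed 4-fold and 92% of those changed 8-fold, with 9 false calls. camera with its preset correlation called 3 of 3 lists shifted 1.5-fold and 0 of 26 others. The estimated correlation and fry were not simulated. The simulated genes varied independently of each other, and libraries of the same number shared no deviation. In the data the estimated correlation within the stress response list was 0.405. The simulation therefore does not show how often camera calls an unshifted list whose genes vary together. The alternatives were pseudocounts of 0.5 and 8, no filter or a limit of 50, TMM scaling, quantile normalization, no variance trend, robust moderation, the replicate number as a block, leaving out each library, and limma-voom on recovered reads, which was added after the data were seen. Negative binomial tests of the recovered reads were planned but not run.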

Results

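The series measured polyadenylated RNA of H1155, a human non-small cell lung carcinoma line with neuroendocrine features, after lentiviral delivery of either an empty vector or a chimeric transcription factor. There were 4 libraries, 2 of the vector and 2 of the chimera. The labels call them biological replicates without saying how the cultures were kept apart, so that p-values measure only the spread between these libraries. The labels do not name the genes joined in the chimera, and its own level was therefore not examined. The deposited table listed 18830 genes as TPM, a transcript abundance relative to gene length and scaled to the same total in each library. The whole reads behind the values amounted to at least 37426748 for vector replicate 1, 27831553 for vector replicate 2, 29717920 for chimera replicate 1 and 29343287 for chimera replicate 2. The title of the series speaks of lineage features and epithelial behaviour, and the comparison of chimera with vector asks which genes of these programmes differ when the factor is present.

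By camera with its preset correlation, 7 of 29 tested gene lists differed between chimera and vector. Integrated stress and unfolded protein response, mesenchymal effector, basement membrane and hemidesmosome, YAP and TEAD target and interferon response genes were higher, and cholesterol synthesis and neuronal cytoskeleton and RNA-binding genes lower. With an estimated correlation 0 lists were called (smallest adjusted p = 0.678), and 0 with fry (smallest adjusted p = 0.468). The estimated correlation leaves camera 2 degrees of freedom, so a list can hardly pass whatever its correlation. Basement membrane and hemidesmosome genes had an estimated correlation of -0.028, yet their unadjusted camera p went from 0.00645 to 0.0957. This setting therefore cannot decide whether correlation between genes accounts for the calls. Without chimera replicate 2 the mean difference of the stress response list turned from 0.37 to -0.037. That fit sets chimera replicate 1 against both vector libraries, so a difference between replicate numbers enters it. Within each replicate number this list was higher in the chimera than in the vector library. The lists of epithelial genes were not called. No single gene passed the test over all genes: of 14550 tested, limma called 0 higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.343. At an unadjusted p under 0.05 there were 802 genes, 583 higher and 219 lower in the chimera, against 728 that chance gives for libraries that vary independently. The same fit on the other splits of the 4 libraries gave 2398 genes at an unadjusted p under 0.05 by replicate number, and 61 for chimera replicate 1 and vector replicate 2 against chimera replicate 2 and vector replicate 1. Between chimera and vector there were 495 higher and 307 lower genes with TMM scaling and 471 higher and 336 lower with quantile normalization. Limma-voom on the recovered reads called 0 genes, with 837 at an unadjusted p under 0.05. With the replicate number as a block, limma called 359 genes higher and 83 lower. The labels do not give libraries of equal number a common culture or day. Both chimera libraries lay above both vector libraries for 2839 tested genes (19.5%) and below both for 2051 (14.1%), where chance gives 16.7% each for libraries that vary independently. The difference was at least 1 on the log2 scale for 70 genes in the upward and 6 in the downward direction. Leaving out vector replicate 2 gave 6 higher and 2 lower genes (TNFRSF9, DDR2, FAM129A, the pseudogene ATP5EP2, ASNS and SLC7A3 higher, KRT19 and TFF1 lower). In vector replicate 2 itself, ATP5EP2 was at 55.9 TPM against 30.8 and 41.1 TPM in the chimera libraries, and KRT19 (0 TPM) and TFF1 (2.67 TPM) were below both chimera libraries, so these 3 calls went against the library left out. Leaving out chimera replicate 1 gave 5 higher and 1 lower (TNFRSF9, DDIT4, DDIT3, NUPR1 and TRIB3 higher, PPP1R17 lower). In chimera replicate 1 itself, DDIT4 (96.3 TPM) and DDIT3 (58.1 TPM) were below both vector libraries. Leaving out chimera replicate 2 gave 2 higher and 1 lower (CCL2 and HOPX higher, PPP1R17 lower). These genes were named after their values were seen.

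The following genes were chosen after their values were seen, for the largest differences among protein-coding genes with an unadjusted p under 0.05 and no overlap between groups. None passed the adjusted threshold. TNFRSF9, a co-stimulatory receptor of the tumour necrosis factor receptor family (GRCh38 chromosome 1, 7915871 to 7940839), was at 38.6 ± 6.61 TPM in the chimera and 6.37 ± 2.89 TPM in the vector libraries (SD, n = 2 each), a difference of 2.47 ± 0.30 (SE) on the log2(TPM + 1) scale. The stress hormone gene GDF15 (chromosome 19, 18386158 to 18389176) was at 33.7 ± 4.61 against 8.72 ± 1.39 TPM, a difference of 1.84 ± 0.19. FGF21, another secreted stress hormone, was at 16.6 ± 8.88 against 3.78 ± 3.36 TPM. FGL1, a secreted fibrinogen-like protein, was at 32.9 ± 1.18 against 8.26 ± 2.63 TPM. SLC7A3, a cationic amino acid transporter, was at 63.8 ± 15.3 against 18.0 ± 11.2 TPM. SLC6A9, a glycine transporter, was at 25.8 ± 10.1 against 7.54 ± 3.61 TPM. The synaptic vesicle gene SV2B was at 7.96 ± 0.51 against 1.75 ± 0.35 TPM. The chemokine CCL2 was at 84.4 TPM in chimera replicate 1 and 18.6 TPM in chimera replicate 2, against 15.0 and 8.55 TPM in the vector libraries. In the other direction, PPP1R17, a regulator of protein phosphatase activity (chromosome 7, 31687215 to 31708455), was at 25.2 ± 6.10 TPM in the chimera and 81.9 ± 8.29 TPM in the vector libraries, a difference of -1.67 ± 0.19. The constitutive chaperone HSPA8 was at 1635 ± 429 against 3199 ± 194 TPM, a difference of -0.99 ± 0.19. BTBD17 was at 4.05 ± 1.28 against 9.47 ± 0.53 TPM. The protocadherin PCDH8 was at 0.45 ± 0.17 against 1.72 ± 0.19 TPM, and the T-box factor TBX2 at 5.02 ± 0.04 against 9.79 ± 1.63 TPM. ZNF423, GABBR2 and HECW2 differed by -0.83 ± 0.21, -0.80 ± 0.28 and -0.78 ± 0.21.

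Epithelial genes did not form a called group. Among 9 tested epithelial transcription and splicing factors the median log2 difference was 0.13 (camera adjusted p = 0.455). It was 0.12 over 19 tight junction and polarity genes (adjusted p = 0.409), 0.024 over 17 adherens junction and desmosome genes (adjusted p = 0.741), -0.013 over 5 keratins (adjusted p = 0.831) and 0.12 over 16 other epithelial surface and trafficking genes (adjusted p = 0.0563). Within each replicate number, the factor, tight junction and other surface lists were on average higher in the chimera than in the vector library. The adherens junction list was lower in chimera replicate 2 and the keratins in chimera replicate 1. In these 5 lists 0 genes passed over all genes, and 1 passed adjusted over the list alone. That gene was MAL2, which encodes a membrane protein of polarized transport (chromosome 8, 119208363 to 119245673), at 83.7 ± 6.40 TPM in the chimera and 39.0 ± 7.09 TPM in the vector libraries, a difference of 1.09 ± 0.15 (SE; limma adjusted p = 0.00643, adjusted over the list alone). E-cadherin (CDH1; chromosome 16, 68737292 to 68835537) was near the floor, with 82 reads in vector replicate 1, 0 in vector replicate 2, 2 in chimera replicate 1 and 1 in chimera replicate 2. KRT19 had 110, 0, 2 and 1 reads in the same order and TFF1 325, 14, 25 and 20, so vector replicate 1 stood apart from the other libraries in these epithelial transcripts. Without it, the CDH1 difference moved from -0.52 to 0.04. The surface marker EPCAM was at 6.34 ± 0.21 TPM in the chimera and 5.93 ± 0.12 TPM in the vector libraries, a difference of 0.08 with a 95% interval from -0.35 to 0.51. The epithelial splicing factor ESRP1 was at 2.98 and 5.18 TPM in the chimera and at 2.66 and 3.08 TPM in the vector libraries. GRHL2, an epithelial transcription factor, was below the limit for testing, with 13, 6, 1 and 2 reads. KLF5 was at 64.5 ± 4.20 against 59.3 ± 10.7 TPM, TJP1 at 72.7 ± 10.2 against 71.6 ± 7.14 TPM, and MLLT4 (afadin, now AFDN) at 99.6 ± 2.28 against 108.2 ± 10.5 TPM. KRT8 was at 74.0 ± 20.7 against 83.1 ± 26.3 TPM.

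**Figure D1:**
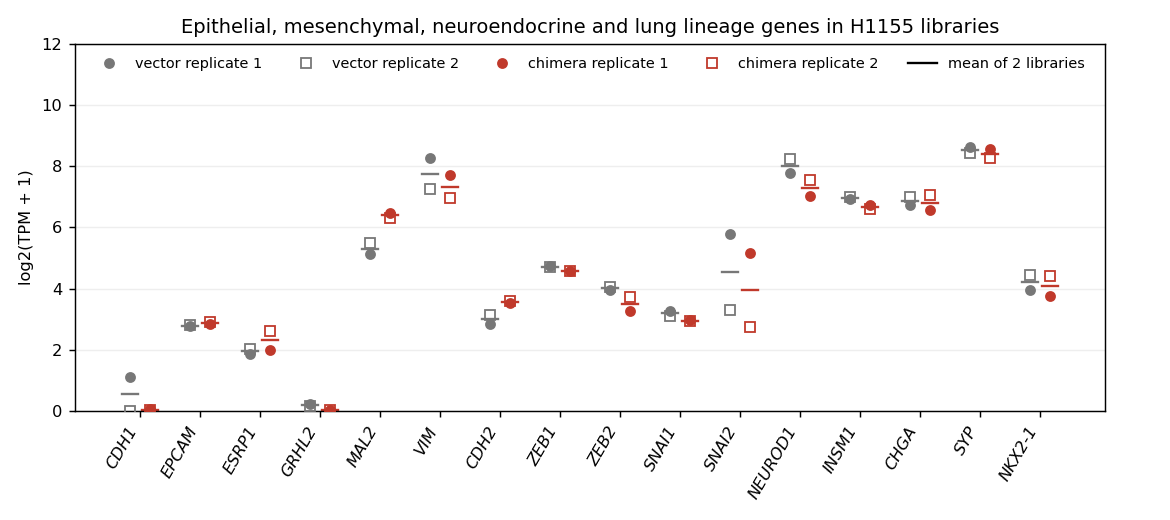
Expression of 16 epithelial, mesenchymal, neuroendocrine and lung lineage genes on the log2(TPM + 1) scale, with each point 1 library and each bar the mean of the 2 libraries of a group (vector grey, chimera red). MAL2 and CDH2 lay higher and NEUROD1 and ZEB2 lower in both chimera libraries than in both vector libraries, and CDH1 was above 1 TPM in vector replicate 1 and in no other library.

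Mesenchymal effector genes rose as a group. Of 29 tested members 24 had a positive difference, the median was 0.18, and camera with its preset correlation gave an adjusted p of 0.0259 (adjusted p = 0.758 with an estimated correlation). Over all genes 0 members passed, and 0 adjusted over the list alone. The members with the largest differences, named after their values were seen, encode matrix proteins and caveolin. COL3A1 was at 7.26 and 2.84 TPM in the chimera against 1.85 and 0.68 TPM in the vector libraries (replicates 1 and 2), and FN1 at 92.6 and 32.6 against 38.8 and 14.6 TPM. COL5A2 was at 7.98 and 3.37 against 4.37 and 1.38 TPM, and CAV1 at 9.04 and 1.74 against 4.02 and 0.64 TPM. These genes were also lower in the libraries with replicate number 2 than in those with number 1, and so was the list, by a mean of -0.33 (camera adjusted p = 0.00302; with an estimated correlation the smallest adjusted p of any list was 0.309). Averaged over the list, log2 levels relative to the mean of the 4 libraries were 0.040 and -0.322 in the vector and 0.294 and -0.012 in the chimera libraries, so vector replicate 1 lay above chimera replicate 2. Within each replicate number the chimera library lay above the vector library. N-cadherin (CDH2; chromosome 18, 27932879 to 28177130) was at 10.8 ± 0.43 TPM in the chimera and 7.01 ± 1.22 TPM in the vector libraries, a difference of 0.56 ± 0.19. Vimentin (VIM) was at 207 and 123 TPM against 308 and 151 TPM (replicates 1 and 2), lower in the chimera library of each number. Its difference of -0.43 became 0.08 without vector replicate 1, where both chimera libraries are set against vector replicate 2. The group's call ended without vector replicate 2 (mean 0.10, adjusted p = 0.785, against 0.28 in all libraries), without chimera replicate 1 (0.13, adjusted p = 0.318) and with genes of a mean of at least 10 TPM only (0.24, adjusted p = 0.193). The mean was 0.463 without vector replicate 1 and 0.435 without chimera replicate 2. The 10 tested transcription factors of mesenchymal transition had a median of -0.046 (adjusted p = 0.455; 0 adjusted over the list alone). ZEB2 was at 10.5 ± 2.50 against 15.1 ± 0.94 TPM. ZEB1 was at 23.0 ± 0.12 against 25.4 ± 0.53 TPM and SNAI1 at 6.77 ± 0.12 against 8.14 ± 0.85 TPM. SNAI2 was at 34.9 and 5.66 TPM in the chimera and 54.2 and 8.77 TPM in the vector libraries (replicates 1 and 2), lower in the chimera library of each number. Its difference of -0.59 was smaller than its SE of 1.02. It became 0.66 without vector replicate 1 and 0.63 without chimera replicate 2, fits that a difference between replicate numbers enters. TCF4 was at 40.0 and 57.1 against 40.1 and 54.2 TPM.

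Neuronal cytoskeleton and RNA-binding genes fell as a group, with 22 of 37 members negative, a median of -0.048 and a camera adjusted p of 0.00488 (adjusted p = 0.758 with an estimated correlation). Adjusted over the list alone 4 members were lower and 0 higher, and over all genes 0. They included TUBB3, the neuronal beta-tubulin (156 ± 5.04 against 245 ± 42.0 TPM), and the neurofilament genes NEFL (213 ± 25.6 against 324 ± 12.8 TPM) and NEFH (23.7 ± 2.01 against 36.4 ± 2.62 TPM), with differences of -0.64 ± 0.13, -0.61 ± 0.11 and -0.60 ± 0.14. The fourth was ELAVL2, a gene of an RNA-binding protein, with a difference of -0.48 ± 0.10. GAP43, a growth cone protein gene, was at 17.6 ± 1.76 against 26.6 ± 3.03 TPM, while MAP1B was at 234 ± 17.3 against 229 ± 10.9 TPM. The list also differed by replicate number, with a mean of 0.15 for number 2 minus number 1 (camera adjusted p = 0.0155; smallest adjusted p of any list 0.309 with an estimated correlation). Its relative log2 levels were -0.033 and 0.134 in the vector and -0.118 and 0.017 in the chimera libraries, so vector replicate 1 lay below chimera replicate 2. Within each replicate number the chimera library lay below the vector library. The group's call ended without vector replicate 2 (mean -0.017, adjusted p = 0.264, against -0.10) and without chimera replicate 1 (-0.033, adjusted p = 0.156). The mean was -0.185 without vector replicate 1, -0.169 without chimera replicate 2 and -0.152 among genes of at least 10 TPM. Of 23 neuroendocrine transcription factors, 11 were positive and 12 negative, with a median of -0.022 (adjusted p = 0.137), and 8 lay lower and 3 higher in both chimera libraries than in both vector libraries. NEUROD1 (chromosome 2, 181668295 to 181680517), a driver of the neuroendocrine lineage, was at 157 ± 39.6 against 260 ± 56.6 TPM, a difference of -0.73 ± 0.21 (adjusted p = 0.75 over all genes). INSM1 was at 101 ± 6.08 against 124 ± 4.76 TPM, a difference of -0.30 ± 0.10. The 1 factor called adjusted over the list alone was SOX2, a lineage factor, at 1.12 and 1.23 TPM in the chimera and 0.109 and 0.224 TPM in the vector libraries, a difference of 0.90 ± 0.14 (limma adjusted p = 0.0163, adjusted over the list alone). SOX2 had 32 and 35 reads in the chimera and 4 and 6 in the vector libraries. Over all genes its limma adjusted p was 0.507. The 35 secretory and synaptic genes had a median of -0.024 and a mean of 0.063, which differ in sign (camera direction up, adjusted p = 0.831). Of these 1, SV2B, passed adjusted over the list alone. CHGA was at 113 ± 26.0 against 115 ± 14.8 TPM, SYP at 341 ± 47.6 against 368 ± 37.1 TPM and PCSK1 at 1045 ± 88.2 against 923 ± 6.58 TPM.

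Among 10 alveolar and airway markers the median of -0.091 and the camera direction were negative and the mean of 0.17 positive (adjusted p = 0.917). Of these 2 were called higher adjusted over the list alone. These were HOPX, at 4.04 and 1.82 TPM in the chimera and 0.326 and 0.198 TPM in the vector libraries (1.58 ± 0.29), and LAMP3, at 18.1 and 17.8 against 5.14 and 8.15 TPM (1.34 ± 0.24). HOPX had 87 and 39 reads in the chimera and 9 and 4 in the vector libraries. NKX2-1, the lung lineage factor, was at 16.5 ± 5.44 against 17.8 ± 4.56 TPM, and LPCAT1 at 51.4 ± 8.12 against 56.9 ± 7.95 TPM. The 9 endoderm and gut lineage factors had a median of 0.047 and a mean of -0.11, again of opposite sign (camera direction down, adjusted p = 0.913), with CDX2 at 6.02 ± 1.17 against 6.32 ± 0.09 TPM. Few markers of other cell types were detected at depth, as 3 of 12 fibroblast and endothelial and 2 of 16 blood cell markers reached the limit for testing, too few for a test of the lists. Their median differences were 0.024 and -0.13.

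Genes of the integrated stress and unfolded protein response rose as a group, with 21 of 27 members positive, a median of 0.38 and a camera adjusted p of 0.019 (adjusted p = 0.828 with an estimated correlation). The members called adjusted over the list alone, 6 higher and 1 lower, were genes of amino acid transport and synthesis, a pseudokinase and a chaperone, and over all genes 0 passed. ASNS, asparagine synthetase (chromosome 7, 97851677 to 97928441), was at 811 ± 93.9 TPM in the chimera and 412 ± 142 TPM in the vector libraries, a difference of 1.01 ± 0.23. The cystine transporter SLC7A11 was at 151 ± 43.2 against 68.0 ± 25.5 TPM. The leucine transporter SLC7A5 was at 186 ± 34.6 against 93.0 ± 22.4 TPM, and the pseudokinase TRIB3 at 293 ± 128 against 130 ± 31.9 TPM. SLC3A2, the partner chain of both transporters, and PSAT1, an enzyme of serine synthesis, differed by 0.78 ± 0.11 and 0.90 ± 0.23. HSPA5, the main chaperone of the endoplasmic reticulum, was lower by the same test, with 337 and 277 TPM in the chimera and 459 and 408 TPM in the vector libraries, a difference of -0.50 ± 0.13. HSP90B1, another chaperone there, was at 1180 ± 51.9 against 1364 ± 51.7 TPM. The 6 negative members also included SDF2L1 (-0.49), MANF (-0.30), PDIA4 (-0.20) and CRELD2 (-0.17), further unfolded protein response genes. Of that response, EDEM1 (0.34), DNAJB9 (0.32), SEL1L (0.31), XBP1 (0.38) and HERPUD1 (0.21) were positive. The rise of the list is therefore not one of its endoplasmic reticulum chaperones HSPA5 and HSP90B1. The transcription factors of the response overlapped between groups and were highest in chimera replicate 2: ATF4 was at 456 and 1120 TPM in the chimera and 463 and 754 TPM in the vector libraries, and DDIT3 at 58.1 and 238 against 64.0 and 85.0 TPM. Averaged over the list, log2 levels relative to the mean of the 4 libraries were -0.35 and -0.026 in the vector and -0.22 and 0.59 in the chimera libraries, so vector replicate 2 lay above chimera replicate 1. Within each replicate number the chimera library lay above the vector library. By replicate number the list differed by a mean of 0.57 for number 2 minus number 1 (camera adjusted p = 0.00173; smallest adjusted p of any list 0.309 with an estimated correlation). Without chimera replicate 2 the mean difference of the list turned from 0.37 to -0.037, with chimera replicate 1 set against both vector libraries. The mean was 0.78 without chimera replicate 1 and 0.21 without vector replicate 1.

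**Figure D2:**
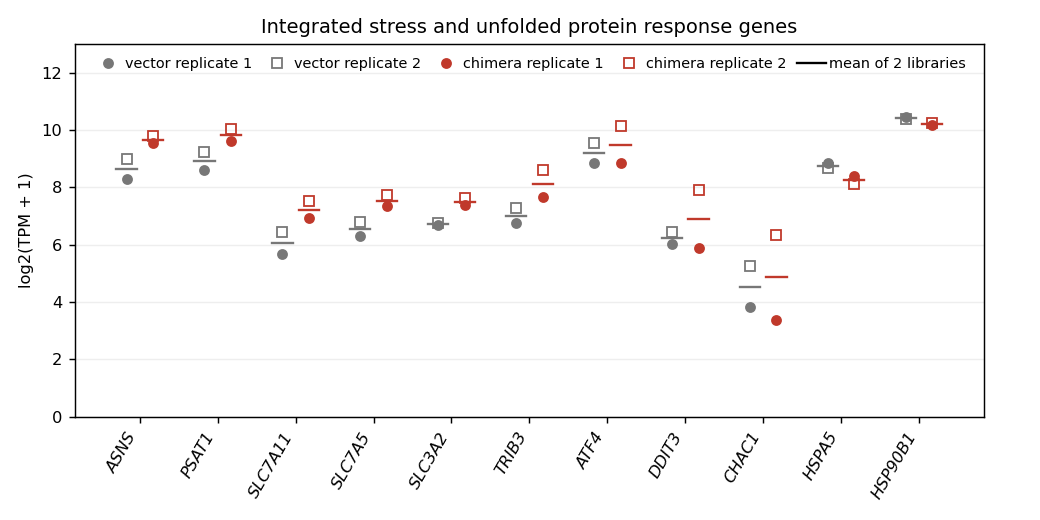
Expression of 11 integrated stress and unfolded protein response genes on the log2(TPM + 1) scale, with each point 1 library and each bar the mean of the 2 libraries of a group. ASNS, PSAT1, SLC7A11, SLC7A5, SLC3A2 and TRIB3 were higher in both chimera libraries than in both vector libraries, ATF4, DDIT3 and CHAC1 overlapped between groups, and HSPA5 and HSP90B1 were lower in both chimera libraries.

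Cholesterol synthesis genes fell as a group: 24 of 28 members were negative, 10 lay below and 0 above the vector libraries in both chimera libraries, and the median was -0.15 (camera adjusted p = 3.98e-05; adjusted p = 0.678 with an estimated correlation). No member passed over all genes, and 0 adjusted over the list alone. Fatty acid synthase (FASN; chromosome 17, 82078338 to 82098236) was at 42.4 ± 0.44 TPM in the chimera and 58.4 ± 1.15 TPM in the vector libraries, a difference of -0.45 ± 0.10. HMGCS1 was at 99.4 ± 10.4 against 125 ± 10.5 TPM. SQLE, the squalene epoxidase gene, was at 112 ± 1.04 against 137 ± 2.86 TPM, and MVK at 13.8 ± 0.36 against 17.3 ± 0.07 TPM. SCD was at 479 ± 7.12 against 500 ± 79.8 TPM. The call held without each library in turn, with mean differences from -0.18 to -0.10.

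Basement membrane and hemidesmosome genes (17 of 22 positive, median 0.15, adjusted p = 0.0312) and YAP and TEAD target genes (17 of 20 positive, median 0.32, adjusted p = 0.0271) rose as groups by camera's preset correlation. For each the adjusted p = 0.678 with an estimated correlation. In the first list 1 member passed adjusted over the list alone, the basement membrane collagen gene COL4A5, at 1.49 and 1.29 TPM in the chimera and 0.422 and 0.447 TPM in the vector libraries. In the second 0 did. ITGA2, an integrin subunit that binds collagen, was at 11.1 ± 2.58 against 6.26 ± 1.67 TPM, and LAMA1 at 1.59 ± 0.25 against 0.68 ± 0.08 TPM. COL4A1 was at 5.96 ± 1.42 against 4.01 ± 0.75 TPM and LAMC1 at 111 ± 18.0 against 107 ± 4.56 TPM. Of the second list, AJUBA was at 44.1 ± 19.0 against 18.3 ± 7.89 TPM and CRIM1 at 2.55 ± 0.40 against 0.92 ± 0.28 TPM. The coactivator gene YAP1 was at 3.22 ± 1.15 against 1.56 ± 0.56 TPM. CTGF (now CCN2) was at 14.5 and 1.59 against 6.01 and 1.12 TPM and TEAD1 at 71.0 ± 3.89 against 70.0 ± 0.20 TPM. The basement membrane call ended without vector replicate 2 (adjusted p = 0.18), without chimera replicate 1 (0.0605), without chimera replicate 2 (0.0786) and among genes of at least 10 TPM (0.231), with means between 0.13 and 0.20 in these settings. The YAP and TEAD call ended without vector replicate 2 (mean 0.22, adjusted p = 0.214), without chimera replicate 1 (0.13, adjusted p = 0.43) and among genes of at least 10 TPM (0.14, adjusted p = 0.878). The mean was 0.30 in all libraries and 0.467 without chimera replicate 2.

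Interferon response genes rose as a group, with 21 of 25 members positive, a median of 0.088 and a camera adjusted p of 0.0378 (adjusted p = 0.678 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. ISG20 was at 7.06 ± 0.62 against 4.04 ± 0.99 TPM and IFI44 at 3.83 ± 0.81 against 2.22 ± 0.13 TPM. IFI35 was at 31.8 ± 0.43 against 21.1 ± 2.75 TPM and the RNA sensor IFIH1 at 10.6 ± 0.91 against 7.12 ± 0.89 TPM. The call ended without vector replicate 2 (mean 0.13, adjusted p = 0.366), without chimera replicate 1 (0.17, adjusted p = 0.187) and without chimera replicate 2 (0.17, adjusted p = 0.0754), against a mean of 0.17 in all libraries. It also ended with quantile normalization (0.11, adjusted p = 0.0707), without a filter (0.13, adjusted p = 0.0736) and among genes of at least 10 TPM (0.056, adjusted p = 0.564).

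The remaining lists were not called by camera. Median differences and adjusted p were 0.14 and 0.0627 for EGFR family receptors and ligands (DUSP6 394 ± 26.5 against 358 ± 3.18 TPM), -0.037 and 0.051 for cell cycle genes (TOP2A 563 ± 69.4 against 542 ± 46.9 TPM) and -0.026 and 0.077 for oxidative phosphorylation genes (ATP5B, now ATP5F1B, 1548 ± 55.7 against 1538 ± 38.9 TPM). They were -0.069 and 0.144 for Wnt pathway genes (TNFRSF19 173 ± 6.77 against 180 ± 10.2 TPM), 0.034 and 0.711 for Notch pathway genes (NOTCH2 20.3 ± 1.25 against 19.9 ± 0.95 TPM), and 0.029 and 0.738 for TGF-beta response genes (ID2 388 and 131 against 556 and 183 TPM). MHC class I genes gave 0.070 and 0.629 (B2M 3393 ± 315 against 3259 ± 287 TPM) and NF-kB and cytokine genes 0.056 and 0.455 (SOD2 141 ± 6.56 against 141 ± 16.4 TPM). The p53 target and apoptosis list gave 0.066 and 0.741, with 2 members higher adjusted over the list alone, GDF15 and the death receptor TNFRSF10B (62.9 and 73.1 against 37.3 and 43.5 TPM), and MCL1 at 280 ± 52.4 against 284 ± 66.4 TPM. For hypoxia and glycolysis genes the median of -0.017 and the camera direction were negative and the mean of 0.056 positive (adjusted p = 0.986; GAPDH 5405 ± 468 against 5928 ± 506 TPM). Cytosolic ribosomal proteins gave 0.066 and 0.144 (RPS4X 4972 ± 211 against 4673 ± 238 TPM) and replication-dependent histone genes -0.35 and 0.409 (HIST1H2BK, now H2BC12, 20.4 ± 0.38 against 32.5 ± 11.2 TPM). Apart from the p53 list, 0 members of the lists in this paragraph passed adjusted over the list alone. Of 13 mitochondrially encoded genes 0 were in the table, and this list was not analysed here.

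**Figure D3:**
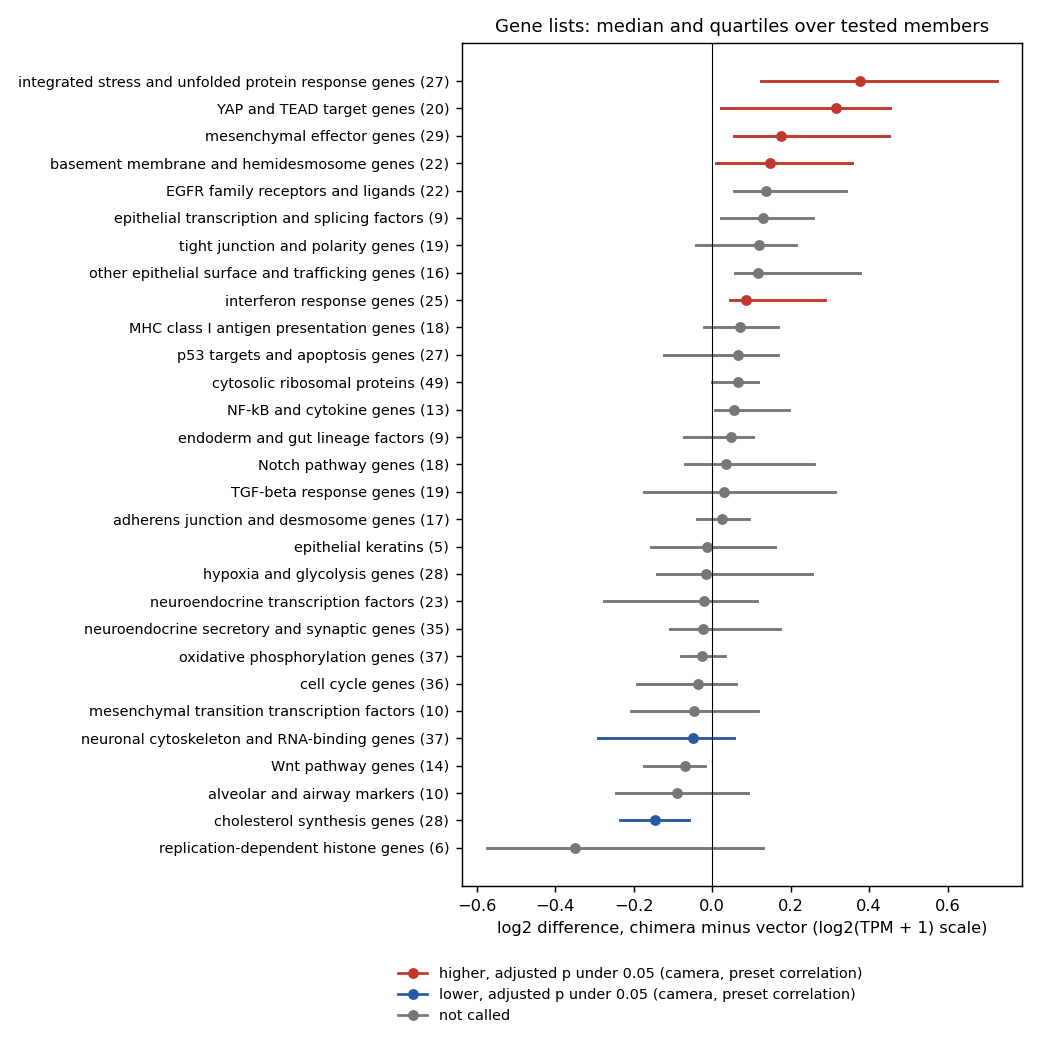
Log2 difference between chimera and vector libraries for the 29 tested gene lists, with the median (point) and the quartiles (line) over tested members, whose number is in parentheses. Of the 7 called lists, 5 (red) were higher and 2 (blue) lower by camera with its preset correlation, and 0 lists were called with an estimated correlation.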

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

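The number of genes called was 0 in both directions, and of those changed at least 2-fold 0, under pseudocounts of 0.5 and 8, no filter, a limit of 50 reads, TMM scaling, quantile normalization, no variance trend, robust moderation, limma-voom and a limit of 10 on the mean TPM, the last pair added after the data were seen. Leaving out each library in turn gave 0 to 6 genes higher, 0 to 2 lower and 0 to 8 changed at least 2-fold; such a fit has 1 library in a group, assumed to vary like the other group. The number of called lists (7 in all libraries) was 3 to 16 when a library was left out, 11 with TMM scaling, 0 with an estimated correlation and 0 with fry, and between 5 and 10 otherwise. A pseudocount of 8, which shrinks differences of genes at low TPM, lowered the means of 4 called lists by over 1.5 times, to 0.133 for mesenchymal effector, 0.118 for YAP and TEAD target, 0.085 for basement membrane and 0.076 for interferon response genes (camera adjusted p = 0.0282 each). TMM scaling and quantile normalization moved the median of all genes from 0.018 to -0.014. Planned tests for counts (edgeR and DESeq2 on recovered reads) were not run, and limma-voom was the only test of the recovered reads. Depth set which genes could be tested, as those under 10 recovered reads were left out.

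The replicate numbers are shared between groups, but the labels give no common culture or day and there are 2 pairs, so they were not taken as pairing. Libraries with the same number deviated together (correlation across genes 0.609). The test without a block counts this shared deviation as spread within groups, so its lack of called genes does not show that no gene differs. With the number as a replicate block limma called 359 genes higher and 83 lower, 72 of them changed at least 2-fold, and 9 lists; limma-voom with the block called 488 higher and 134 lower, 155 of them changed at least 2-fold.

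Each value in this paragraph and the next changed sign under at least 1 setting, and the cause was not tested. TMM scaling gave -0.01 for TJP1, 0.00 for MAP1B, -0.01 for TEAD1, 0.00 for NOTCH2, -0.03 for SOD2 and -0.03 for ATP5B, and quantile normalization gave -0.01 for TJP1, 0.00 for TEAD1, 0.00 for NOTCH2 and 0.01 for MCL1. A limit of 10 on the mean TPM gave a mean of -0.074 for TGF-beta response genes. Leaving out each library in turn, the log2 difference ran for CDH1 from -1.08 to 0.04, VIM from -0.95 to 0.08, SNAI2 from -1.84 to 0.66 and CHGA from -0.28 to 0.19. The range was for SYP from -0.26 to 0.03, NKX2-1 from -0.44 to 0.20, KLF5 from -0.05 to 0.31, TJP1 from -0.12 to 0.16 and KRT8 from -0.48 to 0.17. It was for TCF4 from -0.22 to 0.29, MAP1B from -0.04 to 0.11, LPCAT1 from -0.30 to 0.01, CDX2 from -0.24 to 0.10 and LAMC1 from -0.12 to 0.21. The range was for TEAD1 from -0.04 to 0.07, ID2 from -1.30 to 0.30, NOTCH2 from -0.03 to 0.09, TNFRSF19 from -0.11 to 0.00 and B2M from -0.04 to 0.15. It was for SOD2 from -0.11 to 0.13, TOP2A from -0.07 to 0.18, MCL1 from -0.25 to 0.23, SCD from -0.22 to 0.11 and ATP5B from -0.03 to 0.05. The range was for CAV1 from -0.07 to 1.81, CTGF from -0.58 to 2.01, ATF4 from -0.37 to 0.92, DDIT3 from -0.34 to 1.68 and CHAC1 from -1.15 to 1.81. 

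Mean log2 differences of lists, with a library left out, ran for adherens junction and desmosome genes from -0.018 to 0.127, epithelial keratins from -0.622 to 0.311 and mesenchymal transition transcription factors from -0.212 to 0.031. Further lists ranged, for neuroendocrine transcription factors from -0.161 to 0.049, endoderm and gut lineage factors from -0.296 to 0.086 and TGF-beta response genes from -0.409 to 0.546. Means ran for Notch pathway genes from -0.034 to 0.218, MHC class I antigen presentation genes from 0.000 to 0.154 and NF-kB and cytokine genes from -0.050 to 0.560. Further lists ranged, for p53 targets and apoptosis genes from -0.018 to 0.260, integrated stress and unfolded protein response genes from -0.037 to 0.778 and hypoxia and glycolysis genes from -0.144 to 0.257. Means ran for oxidative phosphorylation genes from -0.077 to 0.000, cytosolic ribosomal proteins from -0.013 to 0.135 and replication-dependent histone genes from -0.423 to 0.065. 

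Over 133 results and these alternatives, 1762 values kept their direction and side of the threshold, 152 kept their direction and newly passed it, 32 no longer passed it and 81 changed sign. The remaining 20, all numbers of called genes or lists, moved by over 1.5 times and are given above.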

Other observations

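Several chaperone genes lay lower in the chimera libraries beyond those named with the largest differences. HSPH1 was at 219 ± 31.2 TPM in the chimera and 339 ± 20.6 TPM in the vector libraries (SD, n = 2 each), and DNAJA1 at 620 ± 142 against 853 ± 25.2 TPM. After HSPA8, HSPH1, DNAJA1 and HSPA5 had been seen, a list of 18 further heat shock chaperones and cochaperones was written and then tested. Of 17 tested, 16 had a negative difference and 12 were lower in both chimera than in both vector libraries, where chance gives 16.7% for libraries that vary independently. Their mean difference was -0.25, which is consistent with a lower level of heat shock chaperones as a group in these libraries (camera p = 9.74e-11 with the preset correlation). The preset correlation takes these genes to vary nearly independently, and with an estimated correlation p was 0.0757. The latter p also rests on only 2 degrees of freedom. It therefore cannot tell whether correlation between these genes accounts for the call. HSP90AA1 differed by -0.37 ± 0.09 (SE), HSP90AB1 by -0.38 ± 0.10, HSPE1 by -0.46 ± 0.09 and AHSA1 by -0.40 ± 0.11, while the collagen chaperone gene SERPINH1 differed by 0.26 ± 0.12. The mean of the list stayed between -0.32 and -0.17 when each library was left out in turn, and was -0.27 with TMM scaling and -0.24 with quantile normalization. This is a hypothesis from the same libraries in which it was first seen, and no technical explanation was tested for it.

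The largest differences in the table followed the replicate numbers rather than the groups. The first principal component, with 56.8% of the variance, placed vector replicate 1 at -23.2, chimera replicate 1 at -10.9, vector replicate 2 at 10.5 and chimera replicate 2 at 23.6, and the second, with 30.7%, placed the vector libraries at -10.2 and -14.5 and the chimera libraries at 19.3 and 5.4. Compared by number, limma called 4 genes at an adjusted p under 0.05 and 2398 at an unadjusted p under 0.05. The 4 were the inhibitors of differentiation ID1 (182 and 94.3 TPM in replicates numbered 1, 5.64 and 6.46 TPM in those numbered 2; vector first) and ID3 (132 and 92.4 against 22.3 and 20.6 TPM), the chemokine IL8 (8.35 and 6.86 against 0.11 and 0.208 TPM) and the zinc transporter SLC30A1 (37.7 and 44.2 against 11.5 and 12.3 TPM). By camera with the preset correlation 10 of 29 lists differed between the numbers, among them TGF-beta response genes (mean log2 difference -0.91, number 2 minus number 1) and hypoxia and glycolysis genes (-0.38). The 10 included 3 of the 7 lists called between chimera and vector, namely integrated stress and unfolded protein response (0.57), mesenchymal effector (-0.33) and neuronal cytoskeleton and RNA-binding genes (0.15). With an estimated correlation 0 differed, and the smallest adjusted p was 0.309.

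For 3 patterns technical explanations were tested. The tests of an epithelial state and of read number in vector replicate 1, and of library size on the first component, were chosen after the values they use had been seen; the others were set beforehand.

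In vector replicate 1, KRT19, CDH1, TFF1 and GATA3 were far above the other libraries, with 558 reads together against 31 in chimera replicate 1, the next library, and GATA3 had 41 reads against 0 to 2. The ratio had a lower 95% exact bound of 12.5, which covers counting error only and lies above the ratio of library sizes of 1.26. This argues against the larger number of reads of that library. Over 54 epithelial genes that the other libraries express, the median log2 difference of vector replicate 1 from those libraries was -0.11 (SD across genes 0.34). This argues against a general rise of the epithelial genes that the other libraries already express. Genes nearly absent there, such as KRT19 and CDH1, were left out of this test. It therefore cannot decide whether silent epithelial genes were turned on in the cells of vector replicate 1. RNA or reads of luminal breast-like epithelial cells may be the source: of 24 luminal markers written down beforehand, 9 had their highest TPM in that library (37.5%, one-sided exact binomial p = 0.121 against 25%) and 8 in chimera replicate 1. This stays open, since these cells express several of the markers themselves; PGR had 12 reads against 1 in each other library and FXYD3 26 against 4, 5 and 2. No other biological explanation was tested.

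The integrated stress list was higher in the chimera libraries and also in those numbered 2. Across its 27 members, which are not independent replicates, the chimera difference followed the difference between numbers with a Pearson r of 0.35 (permutation p = 0.0772, two-sided), and the intercept, the chimera difference at no difference between numbers, was 0.22 with a 95% interval from -0.03 to 0.47. The interval reaches 0, but this test could not decide whether a culture state accounts for the pattern. Both differences count chimera replicate 2 as positive and vector replicate 1 as negative, so a state of either library alone enters both. A shift equal in both libraries of a number would cancel from the chimera difference. A culture state of single libraries cannot be told apart from the chimera. The chimera itself stays among the open explanations.

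The separation of replicate numbers on the first component was not one of library size: the chimera libraries, with a size ratio of 1.01, were 34.5 apart, and the vector libraries, with a ratio of 1.34, were 33.7 apart. Transcript length bias, such as from RNA breakage, stays open, with a Spearman rho of 0.13 across 12447 genes (92.5% of those at a mean of at least 1 TPM), between the bounds set for either reading. No label gives a culture day or library batch, and no biological explanation was tested.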
